A study of Mus musculus with 8 samples.

How the data were processed

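The series measured poly(A) RNA from kidneys of C57BL/6J mice at day 3 after ischaemia-reperfusion injury, 4 libraries after hypoxia and 4 after normoxia before the injury. Per the labels' protocols, flash-frozen kidneys were extracted with Trizol and sequenced from TruSeq stranded mRNA libraries. HISAT2, StringTie and edgeR are named in the processing notes of the submitters, with no versions or roles. The genome build and annotation the authors used are not given in the sources used here. The deposited table gave, per the file headers, FPKM for each gene and library, in 2 decimals, and the authors' FPKM carried no recorded scaling between libraries. Its 34450 Ensembl gene identifiers all matched GENCODE M21 (GRCm38), which supplied symbols, exon lengths and coordinates. Columns after the FPKM values were empty, so no comparison made by the authors was used here. The replicate numbers were taken from the sample titles (1 to 4 for hypoxia, 5 to 8 for normoxia) and did not pair the libraries.

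FPKM was tested as log2(FPKM + 0.5) with no further scaling, in genes with a mean over the 8 libraries of at least 0.5 FPKM. Fold changes on this scale understate those of low genes. The test was the two-sided moderated test of limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, not robust), with a Benjamini-Hochberg adjusted p under 0.05. The 2 groups were the only factor. Every adjusted p of a single gene is from this limma fit. The same step was tested on simulated data for this comparison (14444 genes), where it recovered 57 of 100 genes changed by 2 and 94 of 100 changed by 3 on the log2 scale, none with the wrong sign, with 14 false among 165 calls. The simulation drew independent noise, without the differences in composition between the real libraries.

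Gene lists (45 lists, 765 genes, of which 748 were in the table) for pathways, nephron segments and other cell types were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives listed below unless marked otherwise. Lists with at least 5 tested members (41) were tested with limma's camera at a preset inter-gene correlation of 0.01, and adjusted over the lists. On simulated data, camera called the 1 moved list and none of 40 unmoved lists of 20 genes. That simulation also drew independent noise. It could not show how camera behaves where genes of a list are correlated, as they were in the real libraries. Single members were counted as passing by the adjusted p over all tested genes. The number passing when adjusted over the list alone is given beside it. Library similarity was the mean Spearman correlation within groups less that between groups, with an exact permutation test over the 35 splits.

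Genes were named by a rule. It took the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, mean FPKM of at least 1, groups that do not overlap and a symbol that is not a predicted model. It also took up to 4 passing members of each list, or the 2 with the smallest p where none passed, and 15 genes fixed by name (Ido1, Kmo, Kynu, Havcr1, Lcn2, Vegfa, Epo, Slc34a1, Umod, Adgre1, Ly6g, Cd3e, Pecam1, Col1a1, Mki67). Not every gene that the rule gives is printed.

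Shares of fragments were estimated from FPKM multiplied by exon length. Ribosomal loci were the annotated nuclear and mitochondrial rRNA genes and AY036118, which lies within an annotated rRNA locus on chromosome 17. Read counts were not used here, so depth was estimated from the commonest spacing of low FPKM values times length in single-exon genes of 600 to 3000 bases. This gave 8330000 to 14500000 fragments per library, as an approximation without an interval. The smallest estimated number in protein-coding genes was 1690000 (hypoxia library 3). Low genes were therefore measured on few fragments, and a value listed at 0 is not evidence of absence. None of 46 genes of ribosomal proteins and mitochondrial respiration was listed at 0 in any library.

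Alternatives set in advance were pseudocounts of 0.1 and 1, no filter and a filter of 2 FPKM, scaling by TMM, quantile normalization and a common sum of FPKM, robust and untrended variance, library weights, an adjusted p of 0.10, a minimum log2 change of 1, each library left out, and 3 other list tests. TMM factors, the weighted mean of log ratios between libraries after trimming 30% of the ratios and 5% of the mean levels at each end, were computed in R from the published formula and used as a scaling only. The weights were derived for counts, which FPKM are not. Chosen after seeing the data were TMM scaling without normoxia library 5, removal of each library's trend with exon length (loess, span 0.5), scaling to protein-coding fragments and the ribosomal share as a covariate. Comparison with a table of the authors and count-based tests could not be run, for want of both.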

Results

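Kidney RNA was profiled at day 3 after ischaemia-reperfusion injury (IRI), an interruption and return of renal blood flow that damages mainly the tubules, in 8-week-old C57BL/6J mice. The 4 hypoxia libraries came from kidneys of mice kept in low oxygen before the injury, a treatment known as hypoxic preconditioning. The 4 normoxia libraries came from mice kept in normal oxygen before the same injury. The comparison asks how preconditioning altered the transcriptome of the injured kidney. No uninjured kidney was analysed here, so each difference is between kidneys that all underwent IRI. The labels do not say whether each library came from a separate mouse, and the p-values therefore measure only the spread between these libraries, which may be technical.

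The deposited table held FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of each library) for 34450 genes, of which 14444 had a mean of at least 0.5 FPKM and were tested. No read counts were given. The spacing of the smallest FPKM values placed the depth at roughly 8330000 to 14500000 fragments per library, of which an estimated 1690000 to 8730000 fell in nuclear protein-coding genes. Ribosomal transcripts took 13.5% of the assigned fragments in normoxia library 5 and 72.5% in normoxia library 8, although the libraries were described as poly(A). Their mean share was 49.1% ± 22.03 (SD, n = 4) in the hypoxia libraries and 44.3% ± 28.0 (SD, n = 4) in the normoxia libraries, a difference smaller than the spread within either group (two-sided exact permutation p = 0.771). Normoxia library 5 stood apart, with a mean Spearman correlation with the other libraries of 0.633, against 0.767 to 0.832 for the remaining 7. Its short genes were high and its long genes were low relative to the other libraries, by a median of 1.36 and -0.74 on the log2 scale. Libraries of the same group resembled each other more (mean Spearman correlation 0.814) than libraries of different groups (0.752). The difference of 0.0624 was the largest of the 35 possible splits (one-sided exact permutation p = 0.0286, the smallest this design can give). It missed the threshold when hypoxia library 1, 2, 3 or 4 or normoxia library 7 was left out, with p between 0.0571 and 0.20. The hypoxia libraries lay in pairs, with a Spearman correlation of 0.924 between 1 and 2 and 0.921 between 3 and 4. Across the pairs it was 0.833 to 0.853. Ribosomal shares were 40.9% and 21.5% in hypoxia libraries 1 and 2, and 66.3% and 67.4% in 3 and 4. Why they paired was not tested, and the group may hold fewer than 4 independent samples.

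**Figure D1:**
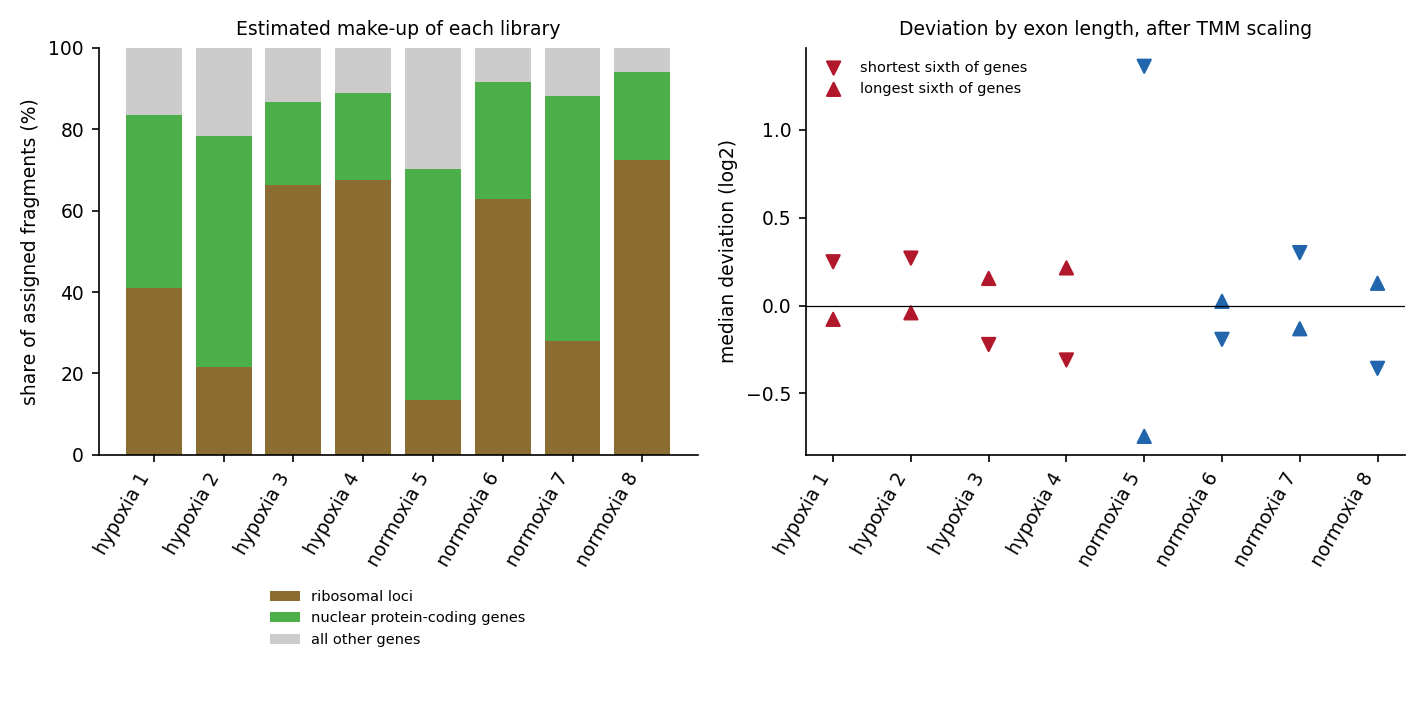
Left, the estimated share of assigned fragments (%) in ribosomal loci, nuclear protein-coding genes and all other genes in each of the 8 libraries. Right, the median log2 deviation from the gene's median over the libraries after TMM scaling, for the shortest (downward triangles) and longest (upward triangles) of 6 classes of exon length, with hypoxia libraries in red and normoxia libraries in blue. Normoxia library 5 lies at 1.36 for short and -0.74 for long genes.

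The counts of genes higher after hypoxic preconditioning and of genes lower after hypoxic preconditioning were 44 and 87. Genes of tubular transport and metabolism were among those with the largest rises, and genes of tubular injury and monocyte recruitment were among those with the largest falls. The groups did not overlap for 124 of these genes. Among all tested genes 711 (4.92%) had groups that did not overlap, where chance gives 2.86%. At an unadjusted p under 0.05, 364 genes were higher and 988 lower. Of the genes past the adjusted threshold 33.6% were higher in the values as deposited. With TMM scaling, which equalises the libraries on the bulk of their genes, 175 were higher and 191 lower (47.8% higher), and with quantile normalization 280 were higher and 349 lower (44.5% higher). TMM scaling moved the median log2 change of all tested genes by 0.15, from -0.14 to 0.016. Single-gene changes below are as deposited, so that a change relative to the median of all genes is more positive by 0.14, and medians of gene lists are given relative to that median. TMM scaling kept the direction and the call of 42 of the 44 higher and 72 of the 87 lower genes. With TMM scaling and without normoxia library 5, 831 genes were higher and 767 lower, among them 44 and 81 of the same genes.

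The counts depended strongly on single libraries. The count of genes higher after hypoxic preconditioning became 26 without hypoxia library 2, 67 without hypoxia library 4 and 11 without normoxia library 7, and the count of genes lower after hypoxic preconditioning became 155, 44 and 54 without hypoxia libraries 1, 3 and 4, and 50, 207, 4 and 237 without normoxia libraries 5, 6, 7 and 8. Without the filter on mean FPKM no gene passed in limma (0 higher, 0 lower of 30982 tested), although 665 were higher and 1356 lower at an unadjusted p under 0.05.

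The largest rise was that of Cyp4a14, a microsomal fatty acid hydroxylase induced by PPAR alpha. It averaged 177.5 ± 284.9 FPKM (SD, n = 4) after hypoxia and 2.90 ± 3.10 FPKM (SD, n = 4) after normoxia, a log2 change of 4.96 ± 0.89 (SE, adjusted p = 0.00648), with 604.7 FPKM in hypoxia library 2 and 30.5 to 41.1 FPKM in the remaining hypoxia libraries. Egf, which encodes the growth factor precursor made in the thick ascending limb and distal convoluted tubule, rose from 2.96 ± 1.54 to 65.9 ± 51.3 FPKM (SD, n = 4 each), a log2 change of 4.12 ± 0.69 (SE, adjusted p = 0.00344). Mettl7a2, a methyltransferase-like gene, rose by 4.18 ± 0.56 (SE) on the log2 scale and was between 9.61 and 40.03 FPKM in the hypoxia libraries and between 0.37 and 0.84 FPKM in the normoxia libraries. Further large rises were those of the brush-border protease gene Mep1b (log2 change 3.71), the organic anion transporter gene Slc22a7 (3.72), Nccrp1 (3.74), the amino acid transporter genes Slc7a13 (3.58) and Slc7a12 (3.51), the aminotransferase gene Aadat (3.46) and Gpx6 (3.22), a glutathione peroxidase gene. Their adjusted p-values lay between 0.00289 and 0.0327. On GRCm38 in the GENCODE M21 annotation, Cyp4a14 (ENSMUSG00000028715) lies on chromosome 4 from 115486200 to 115496142 and Egf (ENSMUSG00000028017) on chromosome 3 from 129677565 to 129755316, both on the minus strand. With TMM scaling Slc7a13 had an adjusted p of 0.0556.

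**Figure D2:**
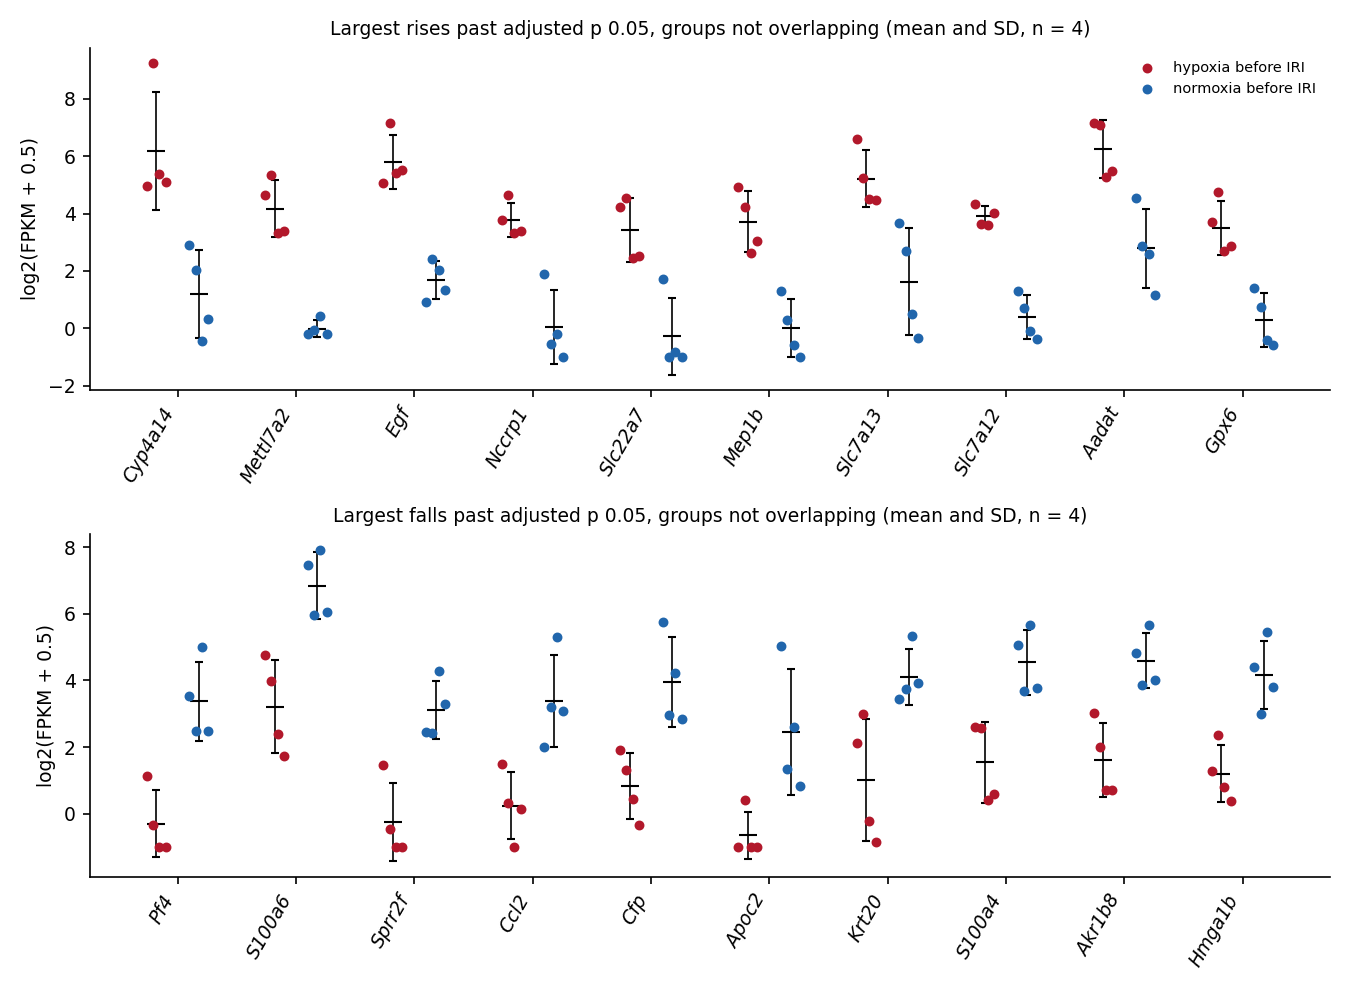
Expression as log2(FPKM + 0.5) in each library for the 10 genes with the largest rises (top) and the 10 with the largest falls (bottom) among genes that passed the test with groups that do not overlap. Points are libraries (red, hypoxia before IRI, and blue, normoxia before IRI), and bars give the mean and SD of 4 libraries. Hypoxia library 2 lies above the other hypoxia libraries for Cyp4a14, at 604.7 FPKM.

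Lists of tubule segment markers were higher after hypoxia with the preset correlation, although only some of their markers passed singly. None of these lists passed as deposited with an estimated correlation. Among 9 tested markers of the thick ascending limb, which reabsorbs salt, 4 rose and none fell, and 5 rose when adjusted over the list alone. They were Egf, Tmem207 (log2 change 2.30 ± 0.41, SE), the dopamine-regulated phosphatase inhibitor gene Ppp1r1b (2.55 ± 0.54) and the prostaglandin receptor gene Ptger3 (2.06 ± 0.44). The median change of the list was 2.20 relative to all genes (camera adjusted p = 2.06e-13, and adjusted p = 0.169 with an estimated correlation). Umod, the most abundant transcript of this segment, averaged 658.2 ± 540.2 FPKM after hypoxia and 326.5 ± 154.8 FPKM after normoxia (SD, n = 4 each) and did not pass (log2 change 0.85, adjusted p = 0.924). Of 12 markers of the distal convoluted and connecting tubule 2 rose, and 3 when adjusted over the list alone, with a list median of 0.91 (adjusted p = 4.14e-08, and adjusted p = 0.169 with an estimated correlation). The 2 were the calcium-binding protein genes Calb1 (log2 change 3.10 ± 0.64, SE) and Pvalb (3.12 ± 0.49). Pvalb was listed at 0 in normoxia libraries 6, 7 and 8. The collecting duct principal cell list (12 tested, median 0.80) had 1 member that rose, the water channel gene Aqp4 (2.05 ± 0.44), and 3 when adjusted over the list alone (adjusted p = 8.59e-05, and adjusted p = 0.244 with an estimated correlation). As deposited, none of 13 intercalated cell markers passed over all genes or adjusted over the list alone, although the list did (median 0.44, adjusted p = 0.0016, and adjusted p = 0.511 with an estimated correlation). Its members with the smallest p were Slc4a1 (log2 change 1.48, adjusted p = 0.207) and Aqp6 (0.98, adjusted p = 0.74). With TMM scaling the numbers higher in these 4 lists were 6, 2, 3 and 0. They were 7, 6, 7 and 3 when adjusted over the list alone, where 1 principal cell gene was lower. With TMM scaling without normoxia library 5 they were 7, 6, 8 and 6 over all genes. The intercalated cell median was then 0.78, against 0.43 with that library.

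In the proximal tubule list, 2 of 24 tested markers rose, Slc22a7 and Slc7a13, and the same number when adjusted over the list alone (median 1.31, adjusted p = 7.24e-14, and adjusted p = 0.187 with an estimated correlation). With TMM scaling 2 rose, and 7 when adjusted over the list alone. With TMM scaling without normoxia library 5, 17 rose over all genes. That library stood apart from its group for this list, with a mean log2 value of 5.98 after TMM scaling, against 3.56 to 5.07 in the other normoxia libraries and 6.11 to 6.51 in the hypoxia libraries. Slc34a1, the sodium-phosphate cotransporter of the proximal tubule, averaged 281.0 ± 87.1 FPKM after hypoxia and 178.4 ± 124.5 FPKM after normoxia (SD, n = 4 each) and did not pass (adjusted p = 0.898). Normoxia library 5 held 340.0 FPKM of it and the other normoxia libraries 37.6 to 180.7 FPKM, and with TMM scaling without that library it passed (log2 change 1.71, adjusted p = 0.0407). Of 18 genes that differ between male and female kidneys, most of them proximal tubular, 5 rose and 9 when adjusted over the list alone (median 2.01, adjusted p = 1.25e-18, and adjusted p = 0.169 with an estimated correlation). They included Cyp4a14, Slc22a7, the fatty acyl-CoA synthetase gene Acsm3 (log2 change 3.21 ± 0.63, SE) and the steroid hydroxylase gene Cyp7b1 (2.59 ± 0.56). Xist was at most 0.02 FPKM, and the Y-linked Ddx3y at least 0.38 FPKM, in all 8 libraries. In the list for solute transport and urinary concentration 1 of 18 genes rose, the organic anion transporter gene Slco4c1 (2.46 ± 0.40), and 7 when adjusted over the list alone (median 1.34, adjusted p = 3.59e-12, and adjusted p = 0.187 with an estimated correlation). In the sex-dimorphic and the solute transport list 4 and 6 genes rose with TMM scaling. When adjusted over the list alone, 10 rose in each and 1 sex-dimorphic gene fell. The numbers over all genes were 12 and 14 with TMM scaling without normoxia library 5.

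Among metabolic lists, 2 of 23 genes of fatty acid oxidation and PPAR alpha targets rose, Cyp4a14 and Acsm3, and 3 when adjusted over the list alone (median 0.999, adjusted p = 6.65e-13, and adjusted p = 0.222 with an estimated correlation). The kynurenine and NAD synthesis list held genes of tryptophan breakdown, of NAD metabolism, and of the aryl hydrocarbon receptor and its targets. Of its 18 tested genes 2 rose and 3 when adjusted over the list alone, and 1 fell only when adjusted in that way (median 0.58, adjusted p = 0.00022, and adjusted p = 0.439 with an estimated correlation). The 2 were Aadat, whose product transaminates kynurenine to kynurenic acid and which averaged 90.3 ± 56.5 FPKM after hypoxia and 9.18 ± 9.17 FPKM after normoxia (SD, n = 4 each), and Ido2, an indoleamine dioxygenase gene, which was low (1.16 ± 0.41 and 0.0575 ± 0.0544 FPKM, log2 change 1.55 ± 0.38, SE, adjusted p = 0.0457). The call of the gene Ido2 was lost with a pseudocount of 0.1 (adjusted p = 0.0636) and of 1 (adjusted p = 0.06). Ido1, whose product starts the breakdown of tryptophan in many tissues, was listed at 0 in 7 libraries and at 0.05 FPKM in hypoxia library 1, and was not tested. Kmo (log2 change 1.80 ± 0.59, SE, adjusted p = 0.181) and Kynu (0.63 ± 0.40, adjusted p = 0.759) did not pass. Transcripts of the mitochondrial genome (13 tested, median 0.96, adjusted p = 9.39e-05) and nuclear genes of mitochondrial respiration (22 tested, median 0.53, adjusted p = 0.00633) were higher as lists with no member passing as deposited over all genes or adjusted over the list alone, and had adjusted p = 0.449 and adjusted p = 0.623 with an estimated correlation. With quantile normalization the list mitochondrially encoded transcripts had an adjusted p of 0.555. Without normoxia library 8 the list mitochondrial respiration (nuclear genes) did not pass (adjusted p = 0.0837). Among their members, mt-Atp6 (log2 change 1.34, adjusted p = 0.55), mt-Cytb (1.09, adjusted p = 0.707) and Ndufs1 (1.06, adjusted p = 0.704) did not pass. The list of NRF2 and antioxidant genes (21 tested, median 0.35, adjusted p = 0.0174, and adjusted p = 0.623 with an estimated correlation) had no member that passed as deposited over all genes or adjusted over the list alone. The list NRF2 and antioxidant genes did not pass without hypoxia library 2 (adjusted p = 0.0829) or normoxia library 8 (adjusted p = 0.0728). Its member with the smallest p, Gpx3, averaged 5432 ± 4971 and 611.8 ± 276.7 FPKM (SD, n = 4 each, adjusted p = 0.178), while Hmox1 went the other way (log2 change -1.62, adjusted p = 0.461, and -1.84 with adjusted p = 0.00836 under TMM scaling without normoxia library 5). The lists of fatty acid oxidation, kynurenine and NAD synthesis, mitochondrially encoded transcripts, mitochondrial respiration and NRF2 had 4, 2, 0, 0 and 0 members higher with TMM scaling. The numbers were 11, 5, 0, 1 and 4 when adjusted over the list alone, and 13, 7, 9, 5 and 5 over all genes with TMM scaling without normoxia library 5. In each of the latter 2 settings 1 kynurenine and 1 NRF2 gene were lower. Leaving that library out under TMM scaling moved the medians of the last 3 lists from 1.03 to 1.58, from 0.58 to 0.90 and from 0.41 to 0.72.

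Genes of tubular injury were lower after hypoxia as a list with the preset correlation. Of 19 tested, 5 fell and none rose, and 16 fell when adjusted over the list alone, with a list median of -2.22 (adjusted p = 1.25e-18, and adjusted p = 0.169 with an estimated correlation). Timp1, an inhibitor of matrix metalloproteinases, had the largest fall, from 71.8 ± 100.3 to 2.97 ± 4.01 FPKM (SD, n = 4 each, log2 change -4.03 ± 0.88, SE, adjusted p = 0.0252). Normoxia library 5 held 220.5 FPKM of it, the groups overlapped, and with TMM scaling its adjusted p was 0.0746. The other 4 were S100a6 (log2 change -3.64 ± 0.82, SE), the keratin gene Krt20 (-3.10 ± 0.73), the hyaluronan receptor gene Cd44 (-2.46 ± 0.57) and Sox9 (-2.14 ± 0.45), a transcription factor induced in regenerating tubule cells. The calls of Krt20 and Cd44 were lost with a pseudocount of 1. Havcr1, which encodes kidney injury molecule 1, averaged 36.6 ± 45.5 FPKM after hypoxia and 232.3 ± 167.1 FPKM after normoxia (SD, n = 4 each) and did not pass (log2 change -3.37 ± 0.94, SE, adjusted p = 0.0855). Lcn2, a second urinary injury marker, averaged 7.96 ± 6.72 and 76.4 ± 88.3 FPKM and did not pass either (-2.97 ± 0.83, adjusted p = 0.0855). Normoxia library 5 held 206.6 FPKM of Lcn2 and the other normoxia libraries 20.4 to 55.9 FPKM. With TMM scaling without that library, Lcn2 (-2.02, adjusted p = 0.0193) and Havcr1 (-3.53, adjusted p = 0.022) passed. In the failed-repair proximal tubule list, 1 of 11 genes fell, Ccl2, and 5 when adjusted over the list alone (median -0.89, adjusted p = 1.80e-06, and adjusted p = 0.245 with an estimated correlation). S100a4 (-3.0 ± 0.69), the neighbour of S100a6 on chromosome 3, also fell, as did the aldo-keto reductase gene Akr1b8 (-2.98 ± 0.68) and the cornified-envelope gene Sprr2f (-3.36 ± 0.57). In the tubular injury and the failed-repair list 6 and 1 genes fell with TMM scaling. The numbers were 15 and 6 when adjusted over the list alone, and 14 and 5 over all genes with TMM scaling without normoxia library 5.

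Genes of the cell cycle were lower as a group. Of 24 tested, 9 fell and none rose, and 22 fell when adjusted over the list alone (median -1.74, adjusted p = 4.73e-29, and adjusted p = 0.169 with an estimated correlation). Mki67, the proliferation marker, fell from 13.3 ± 7.07 to 1.26 ± 0.996 FPKM (SD, n = 4 each, log2 change -2.94 ± 0.58, SE, adjusted p = 0.0148). The cyclin genes Ccna2 (-2.77 ± 0.59) and Ccnb1 (-2.34 ± 0.49) and the replication helicase gene Mcm5 (-2.57 ± 0.54) were also among the 9. Replication-dependent histone genes, expressed during DNA synthesis, had 2 of 9 tested members that fell, Hist1h3c (-2.44 ± 0.41) and Hist1h1b (-2.30 ± 0.52), and 7 when adjusted over the list alone (median -1.42, adjusted p = 4.68e-06, and adjusted p = 0.169 with an estimated correlation). With TMM scaling Hist1h1b had an adjusted p of 0.0959, and 3 members were lower and 2 higher when adjusted over the list alone. The call of Hist1h1b was also lost with a pseudocount of 1. In the cell cycle and the histone list 14 and 1 genes fell with TMM scaling (23 in the cell cycle list when adjusted over the list alone). The numbers were 24 and 2 with TMM scaling without normoxia library 5, where 1 histone gene rose. The histone list passed narrowly in that setting (camera adjusted p = 0.0488). It is among the lists given below that lost their call in an alternative. Histone transcripts lack the usual poly(A) tail, so their level in poly(A) libraries may depend on how much RNA without a tail was kept. That was not tested. Histone genes are near-identical copies, and Hmga1b (-2.96 ± 0.64) resembles Hmga1, so the assignment of reads to single members is uncertain.

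Genes of monocyte recruitment and macrophages were lower as lists with the preset correlation, although few of them passed singly as deposited. Of 19 tested chemokine and chemokine receptor genes 5 fell and none rose, and 11 fell and 1 rose when adjusted over the list alone (median -1.33, adjusted p = 6.75e-13, and adjusted p = 0.187 with an estimated correlation). The monocyte-attracting chemokine gene Ccl2 fell from 14.7 ± 16.2 to 0.915 ± 0.974 FPKM (SD, n = 4 each, log2 change -3.15 ± 0.64, SE, adjusted p = 0.0172). Ccl12 (-2.58 ± 0.53), Ccl7 (-2.45 ± 0.53) and Ccl6 (-2.82 ± 0.56) also fell. On GRCm38, Ccl2 (ENSMUSG00000035385), Ccl7 and Ccl12 lie together on chromosome 11 between 82035571 and 82103400. Of 23 macrophage and monocyte genes 2 fell, Chil3 (-2.68 ± 0.55), a marker of recruited myeloid cells, and the Fc receptor gene Fcgr1 (-2.18 ± 0.48), and 19 when adjusted over the list alone (median -1.58, adjusted p = 8.51e-18, and adjusted p = 0.178 with an estimated correlation). Adgre1, which encodes F4/80, averaged 1.03 ± 0.68 and 3.86 ± 2.28 FPKM (SD, n = 4 each) and did not pass as deposited (adjusted p = 0.181), but passed with TMM scaling (log2 change -1.42, adjusted p = 0.0353). The platelet factor gene Pf4 (-3.68 ± 0.59), the properdin gene Cfp (-3.11 ± 0.67) and the apolipoprotein gene Apoc2 (-3.10 ± 0.64) fell. With TMM scaling Apoc2 had an adjusted p of 0.0834. In the chemokine and the macrophage list 7 and 5 genes fell with TMM scaling. The numbers were 14 and 20 when adjusted over the list alone, and 11 and 16 over all genes with TMM scaling without normoxia library 5. In each of these settings 1 gene of the chemokine list rose.

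The NF-kappaB and acute inflammation list had 1 of 14 members that fell, Ccl2, and 8 when adjusted over the list alone (median -1.03, adjusted p = 3.91e-09, and adjusted p = 0.244 with an estimated correlation). Complement and coagulation genes had 2 of 24 that fell, among them Cfp, and 6 when adjusted over the list alone (median -0.42, adjusted p = 0.0181, and adjusted p = 0.623 with an estimated correlation). In the list for pyroptosis, necroptosis and ferroptosis 2 of 15 genes fell, the necroptosis genes Ripk3 (-1.86 ± 0.45) and Mlkl (-1.79 ± 0.43), and 3 when adjusted over the list alone (median -0.46, adjusted p = 0.00148, and adjusted p = 0.511 with an estimated correlation). With a pseudocount of 1 the gene Ripk3 and the gene Mlkl did not pass (adjusted p = 0.0672 for both), and with a filter of 2 FPKM the list pyroptosis, necroptosis and ferroptosis did not (adjusted p = 0.602). With TMM scaling its median was -0.40, and -0.15 without normoxia library 5. Extracellular matrix and fibrosis genes had 1 of 23 that fell, Timp1, and 17 when adjusted over the list alone (median -1.45, adjusted p = 3.02e-13, and adjusted p = 0.187 with an estimated correlation). Col1a1, the main fibrillar collagen gene, averaged 7.42 ± 3.26 and 46.8 ± 30.04 FPKM (SD, n = 4 each) and did not pass (log2 change -2.48 ± 0.70, SE, adjusted p = 0.0882), but passed with TMM scaling (adjusted p = 0.0179). The lists of NF-kappaB, complement, cell death and extracellular matrix had 1, 3, 2 and 9 members lower with TMM scaling. The numbers were 9, 6, 6 and 16 when adjusted over the list alone, and 9, 8, 3 and 18 over all genes with TMM scaling without normoxia library 5. The list complement and coagulation did not pass without hypoxia library 3 (adjusted p = 0.0792), hypoxia library 4 (adjusted p = 0.0871) or normoxia library 6 (adjusted p = 0.0733).

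Lists of other cell types and of stress were called without a member that passed as deposited. The neutrophil list (7 of 17 members tested) had a median of -1.54 and 5 members lower when adjusted over the list alone (adjusted p = 9.13e-05, and adjusted p = 0.244 with an estimated correlation). Its members with the smallest p were Lcn2, also given above as an injury marker (log2 change -2.97, adjusted p = 0.0855), and Csf3r (-1.68, adjusted p = 0.16). Csf3r was 10.05 FPKM in normoxia library 7 and 0.72 to 0.88 FPKM in the other normoxia libraries. Ly6g was not analysed here. Interferon-stimulated genes (21 tested, median -0.95, 3 lower when adjusted over the list alone) had an adjusted p of 4.44e-06, and adjusted p = 0.36 with an estimated correlation, with Oas1a (-2.13, adjusted p = 0.0676) and Oasl1 (-1.84, adjusted p = 0.078) as the members with the smallest p. The fibroblast, pericyte and smooth muscle list (16 tested, median -0.51, 4 lower when adjusted over the list alone) had adjusted p = 0.00578, and adjusted p = 0.587 with an estimated correlation, and its member Col3a1 had a log2 change of -2.23 (adjusted p = 0.162, and adjusted p = 0.0422 with TMM scaling). The lists of ribosomal proteins (24 tested, median -1.0, adjusted p = 0.000482), antigen presentation (15 tested, -0.66, 0.00111), the unfolded protein response (17 tested, -0.57, 0.0129) and immediate early and heat shock genes (17 tested, -0.59, 0.0272) were lower, and their adjusted p with an estimated correlation was 0.623, 0.522, 0.623 and 0.623. As deposited, none of their members passed over all genes or adjusted over the list alone, including Rps19 (-1.52, adjusted p = 0.639) and Rpl10a (-1.54, adjusted p = 0.689). Erythroid genes (8 tested, median 1.93, 3 higher when adjusted over the list alone, adjusted p = 3.04e-09), adipose tissue genes (9 tested, 0.83, 0.000477) and the circadian clock (15 tested, 0.25, 0.0359) were higher, and their adjusted p with an estimated correlation was 0.169, 0.244 and 0.623. No adipose or circadian member passed over all genes or adjusted over the list alone. The mean log2 value of the adipose list after TMM scaling was 0.48, 0.25, 3.10 and 1.54 in hypoxia libraries 1 to 4 and 1.44, 0.92, -0.08 and -0.36 in normoxia libraries 5 to 8. Hypoxia library 3 stood highest, and 2 hypoxia libraries lay below 2 normoxia ones. The change of the list adipose tissue relative to other genes (a mean of 0.86) was 0.33 without hypoxia library 3 and did not pass (adjusted p = 0.193). It was 1.33 without hypoxia library 2 and 0.53 without normoxia library 7. The list circadian clock did not pass without hypoxia library 2 (adjusted p = 0.133), hypoxia library 3 (adjusted p = 0.0666), normoxia library 5 (adjusted p = 0.07) or normoxia library 8 (adjusted p = 0.103). The list immediate early and heat shock genes did not pass without hypoxia library 4 (adjusted p = 0.0856), normoxia library 6 (adjusted p = 0.0966) or normoxia library 7 (adjusted p = 0.0844). The mean change of the list antigen presentation went from -0.72 to -0.42 without normoxia library 5. The erythroid members with the smallest p were the globin genes Hbb-bt (44.9 ± 25.4 and 6.62 ± 4.98 FPKM, SD, n = 4 each, adjusted p = 0.0648) and Hbb-bs (108.7 ± 47.5 and 19.9 ± 19.4 FPKM, adjusted p = 0.0995), which passed with TMM scaling (adjusted p = 0.03 and adjusted p = 0.0438). With TMM scaling the median of the erythroid list was 1.98, and 3.62 without normoxia library 5. The corresponding medians of the ribosomal protein list were -0.95 and -0.42, and as deposited the list ribosomal proteins did not pass without normoxia library 5 (adjusted p = 0.122). Leaving that library out under TMM scaling moved the medians of the interferon and circadian lists from -0.94 to -0.62 and from 0.30 to 0.16. The neutrophil, interferon, fibroblast, unfolded protein response and immediate early lists had 0, 0, 4, 0 and 0 members lower with TMM scaling. They had 4, 5, 5, 4 and 3 when adjusted over the list alone, and 1, 3, 6, 1 and 5 over all genes with TMM scaling without normoxia library 5. The erythroid list had 2, 4 and 5 higher in these settings, and the lists of ribosomal proteins, antigen presentation, adipose tissue and the circadian clock had none.

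**Figure D3:**
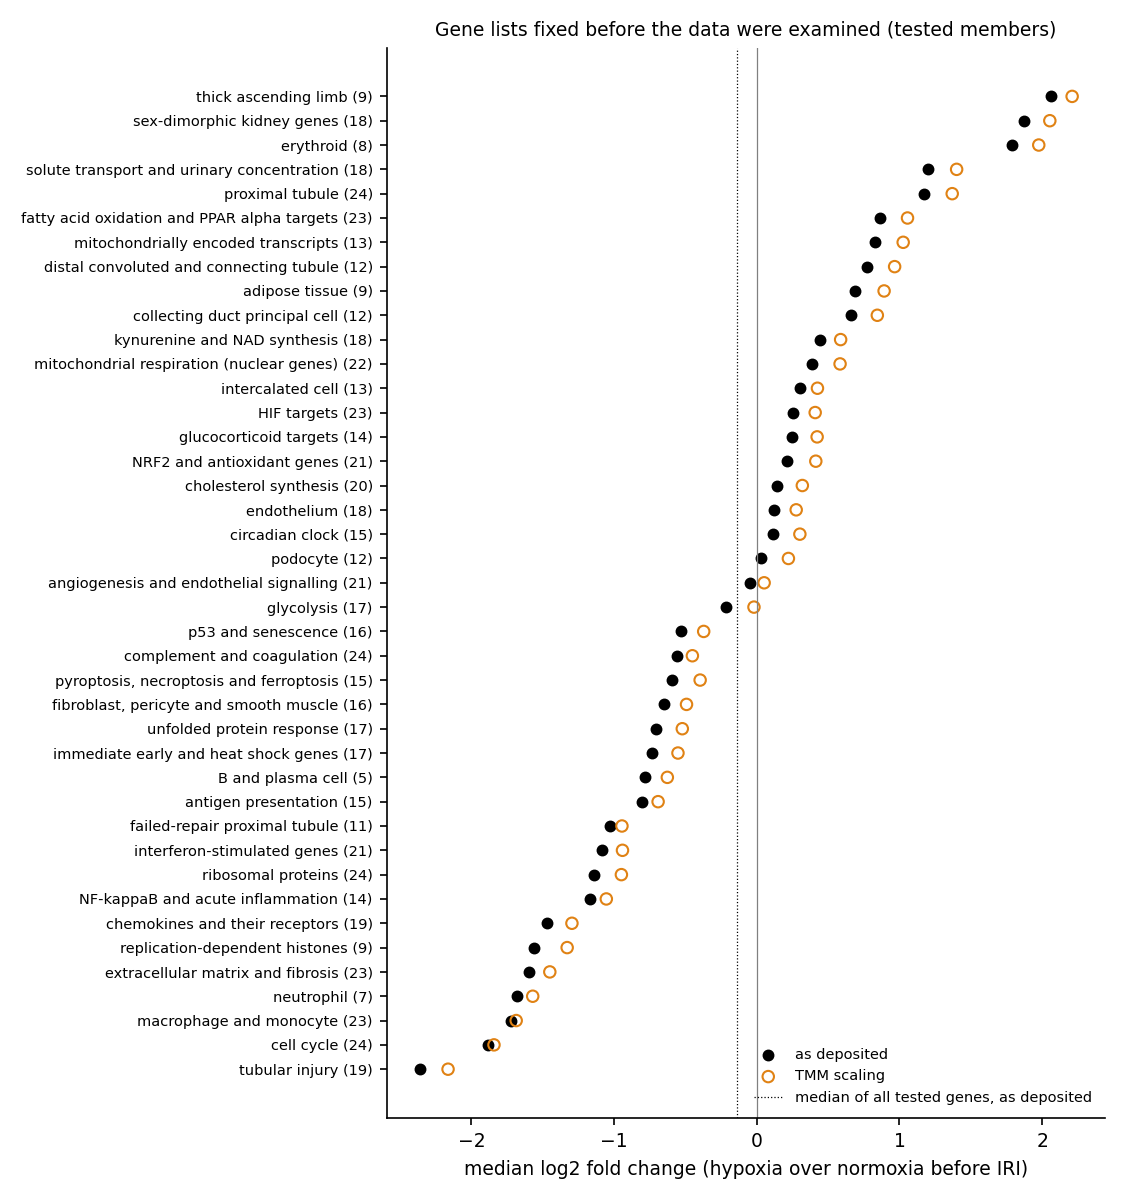
Median log2 fold change of the tested members of each of 41 gene lists (number tested in brackets), as deposited (filled circles) and with TMM scaling (open circles), with the median of all tested genes as deposited as a dotted line at -0.14. Tubular injury and cell cycle genes lie lowest, and the thick ascending limb highest, at 2.06 as deposited.

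HIF targets, the genes induced by low oxygen, did not pass as a list (23 tested, median 0.39, adjusted p = 0.194). Vegfa averaged 18.4 ± 8.04 and 9.69 ± 6.03 FPKM (SD, n = 4 each, adjusted p = 0.81) and Epo 0.545 ± 0.239 and 1.02 ± 1.09 FPKM (adjusted p = 0.983). Lists of endothelium (18 tested, adjusted p = 0.0902), p53 and senescence (16, 0.104), cholesterol synthesis (20, 0.176), B and plasma cells (5, 0.291), podocytes (12, 0.371), glucocorticoid targets (14, 0.468), glycolysis (17, 0.833) and angiogenesis (21, 0.847) also did not pass as deposited. With TMM scaling the endothelium and cholesterol synthesis lists passed (both higher, adjusted p = 0.0294 for each), so that 34 lists passed in all. With TMM scaling without normoxia library 5, p53 and senescence (lower, adjusted p = 0.0259), cholesterol synthesis (higher, adjusted p = 0.0235) and glycolysis (higher, adjusted p = 0.0174) passed and endothelium did not (adjusted p = 0.0791). For podocytes, glucocorticoid targets, glycolysis and angiogenesis the mean log2 change, not taken relative to all genes, was negative although the direction of the test was higher. Their medians relative to all genes were 0.17, 0.38, -0.079 and 0.092, so that only glycolysis differed from its test. Hk2 (log2 change -1.42, adjusted p = 0.115) of glycolysis and Vcam1 (-2.58, adjusted p = 0.0872) of angiogenesis did not pass. The endothelial gene Pecam1 averaged 4.93 ± 2.34 and 4.95 ± 2.92 FPKM (adjusted p = 0.999). Cd3e was between 0 and 0.24 FPKM, below the filter, and the lists of T and NK cells (1 tested member), adrenal gland (2), skeletal muscle (4) and sex-linked transcripts (4) were too small to test.

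In all, 15 of the 41 tested lists were higher and 17 lower. As deposited, none of the 32 passed with an estimated correlation between genes, which lay between 0.12 and 0.932 against the preset 0.01, nor in an exact permutation test of list means, whose smallest p of 0.0286 was reached by 9 lists. With TMM scaling 3 lists passed with an estimated correlation, the extracellular matrix (adjusted p = 0.00993), the thick ascending limb (adjusted p = 0.0181) and the distal convoluted and connecting tubule (adjusted p = 0.0229). With TMM scaling and without normoxia library 5, 31 of the 32 kept their direction and passed, and the circadian clock did not (adjusted p = 0.0791). Under the same setting 15 of the genes given above as not passing passed, although not with TMM scaling of all libraries: Slc4a1, Hmox1, Ndufs1, Aqp6, Kmo, Hk2, Vcam1, Lcn2, Vegfa, Havcr1, mt-Atp6, mt-Cytb, Gpx3, Oas1a and Slc34a1 (adjusted p from 0.00403 to 0.0407).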

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

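The splits of all 8 libraries were set before the results were seen, and the other tests were chosen after: those on normoxia library 5 (exon length, ribosomal share, wrong label, each library held out), the splits and the genes kept without it, ribosomal dilution and infiltrating cells.

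For each named gene, list mean and library measure, the 4 libraries of each group were searched for a value far from the other 3, and 7 of 246 such groups held one, where chance flags about 1 in 20. In hypoxia library 2, Cyp4a14 stood at 604.7 FPKM (gap over range 0.901) and Apoc2 at 0.82 FPKM with the other 3 hypoxia libraries listed at 0 (ratio 1). In normoxia library 5, Pvalb stood at 1.42 FPKM with the other 3 listed at 0 (ratio 1), and Slc22a7 at 2.78 FPKM (0.94). Csf3r was 10.05 FPKM in normoxia library 7 (0.943), and Gpx3 was 202.1 FPKM in normoxia library 8 (0.895). The mean of the fatty acid oxidation and PPAR alpha list was also low in normoxia library 8 (2.20 on the log2 scale against 3.39 to 3.60, ratio 0.852).

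The first pattern is the number of genes and lists called between the groups. As deposited, 2 of the 35 splits of the 8 libraries called at least as many genes as the real split (44 higher and 87 lower), so chance cannot be excluded for that count. The other split put hypoxia libraries 1 and 2 with normoxia libraries 5 and 7 and called 3085 genes, which points to a structure of the samples: these are the 4 libraries with the smallest ribosomal share, and with that share as a covariate the real split called 90 higher and 191 lower. With TMM scaling only 1 split, the real split, reached its 366 genes and the highest other called 2. With TMM scaling without normoxia library 5 only 1 of 35 reached 1598 (highest other 488). The split with 488 put hypoxia libraries 3 and 4 with normoxia libraries 6 and 8, the 4 libraries with the largest ribosomal share. The structure by ribosomal share was therefore still seen in that setting. Both settings with TMM scaling argue against chance without excluding it, since 35 splits give an exact permutation p of 0.0286 at the smallest. The setting without library 5 was also chosen after seeing the data. For the lists only 1 split, again the real split, reached 32, but others called up to 28 and a median of 14.5, so that a single list called with the preset correlation is weak evidence.

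The second pattern is the distance of normoxia library 5 from the rest. Removing each library's trend with exon length left its mean Spearman correlation at 0.656 (0.633 before), under the lowest of the other 7 (0.78), which argues against that trend as the whole cause. A low ribosomal share is argued against by the 2 libraries with the next lowest shares, whose lowest mean correlation was 0.791. A wrong label on a library that otherwise follows the hypoxia group is argued against. Library 5 lay nearer the normoxia mean for 48.5% of 1589 genes called without it (exact 95% interval 46.0 to 50.9%), whereas the hypoxia libraries, each held out in the same way, did so for at most 19.0% of genes. The other normoxia libraries did so for 78.7 to 95.7%, so that library 5 followed neither group. Of 28 lists whose groups did not overlap without it, it lay nearer the normoxia mean for 14. Among these were the thick ascending limb (2.40, against 2.31 to 2.68 in the other normoxia and 4.23 to 4.73 in the hypoxia libraries), the extracellular matrix (3.45, against 3.41 to 3.73 and 2.0 to 2.24) and tubular injury (5.58, against 4.35 to 4.89 and 1.87 to 3.39). It lay nearer the hypoxia mean for the other 14, among them the proximal tubule and mitochondrially encoded transcripts. Any other wrong label, such as that of a sample from outside the 2 groups, cannot be told apart from an altered normoxia library, since 48.5% is where a library that follows neither group would lie. Differences in RNA integrity or in the animal stay open and were not tested.

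The third pattern is that lists of tubule genes were higher while lists of injury, cell division and chemokine genes were lower. Dilution by ribosomal fragments moves all other genes of a library in the same direction, and low genes less on this scale. It is argued against only weakly as the whole cause, since lists moved in opposite directions. Mean log2 changes as deposited ran from 0.47 (intercalated cell) to 1.82 (thick ascending limb) in the tubule segment lists. They were -2.36, -2.01 and -1.48 for tubular injury, cell cycle and chemokines. The changes of the 41 tested lists moved apart with an SD of 1.09, against at most 0.85 in the other 34 splits. The exact permutation p was 0.0286, the smallest possible, and the same over 40 or 41 lists with each single library left out. This SD test was chosen after the changes were seen and restates them. It did not allow for low genes moving less, so it does not decide on dilution. Library 5 as the sole source is argued against under TMM scaling, where 95.4% of the 44 higher and 87 lower genes kept their direction and call without it. The exact 95% interval of 90.3 to 98.3% counts genes as independent, which they are not. The scaling changed as well, so this share does not give the effect of the library alone. As deposited, leaving out library 5 lowered the count of lower genes, as given above. It ended the call of 16 of the 47 named genes that passed, and reversed none of them. Infiltrating cells that dilute all kidney cell types alike are argued against only weakly as the whole cause. The changes of the 7 lists of nephron segments, podocytes and endothelium moved apart after TMM scaling with an SD of 0.69, against at most 0.57 in the other splits (exact permutation p = 0.0286). The test was chosen after these changes were seen and restates them, and it did not allow for low genes moving less on this scale. That test missed the threshold without hypoxia library 1, 2, 3 or 4 (exact permutation p = 0.0571 each), where 1 other split gave a larger SD. Less injured or further recovered tubules at day 3 after preconditioning stay open as an untested explanation, as does a difference between the animals, and no test run here separates them.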

How the results depend on the processing

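The alternatives with exon length, protein-coding scaling, the ribosomal covariate and TMM without normoxia library 5 were chosen after seeing the data, and their causes were not tested unless stated. No paired analysis was possible because the groups share no replicate number. Agreement with a table of the authors and count tests were not run, since neither a comparison nor counts were given. The counts of genes higher after hypoxic preconditioning and genes lower after hypoxic preconditioning (44 and 87) became 175 and 191 with TMM, 280 and 349 with quantile normalization, 207 and 257 with exon length removed, 148 and 228 on protein-coding fragments, 90 and 191 with the ribosomal covariate, 831 and 767 with TMM without normoxia library 5, 17 and 8 without the variance trend, 360 and 1297 with library weights and 74 and 201 at adjusted p 0.10. Lower genes alone moved to 47 with pseudocount 1 and 163 with a common sum of FPKM. Without the filter 0 and 0 passed in limma (665 and 1356 at unadjusted p under 0.05). Leaving out single libraries gave 11 to 67 higher and 4 to 237 lower genes, both lowest without normoxia library 7. Lists called were 12 to 16 higher and 15 to 18 lower with single libraries left out, and 0 and 0 with an estimated correlation, fry or exact permutation of list means (5 and 4, 5 and 8, and 3 and 6 at unadjusted p under 0.05). With 41 lists at a smallest permutation p of 0.0286, 9 lists at that value do not reach an adjusted p under 0.05. The difference in library similarity (0.0624) was 0.0172 without the filter (exact permutation p = 0.0571), and ranged from 0.0322 to 0.0948 with single libraries left out. Of 47 genes that the naming rule gave and that passed, none changed sign in any alternative tried, 39 stayed past the threshold under each of TMM, quantile, common-sum and protein-coding scaling, and 8 did with each single library left out. With a pseudocount of 1 the calls of Hist1h1b, Cd44, Krt20, Ripk3, Mlkl and Ido2 were lost, and with 0.1 that of Ido2. Apart from other list tests, 10 lists lost the call in at least 1 alternative: NRF2, circadian clock, histones, cell death (pyroptosis, necroptosis, ferroptosis), immediate early, mitochondrially encoded, adipose, complement, ribosomal protein and mitochondrial respiration genes. The gene Pecam1 (0.037) changed sign to -0.045 with a common sum of FPKM, -0.23 without hypoxia library 2, -0.11 and -0.12 without normoxia libraries 5 and 8, and -0.10 with library weights (-0.23 to 0.36 with single libraries left out), and the gene Epo (-0.33) to 0.018 with exon length removed and 0.098 without normoxia library 7 (-0.60 to 0.098). Depth limits low genes most, with as few as 1690000 estimated protein-coding fragments.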

Other observations

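The genes in these paragraphs were chosen, and both family tests made, after the values were seen. The stearoyl-CoA desaturase gene Scd1 averaged 15.0 ± 3.47 FPKM after hypoxia and 2.03 ± 1.42 FPKM after normoxia (SD, n = 4 each, log2 change 2.76 ± 0.58, SE). Cyp2a4, a steroid hydroxylase gene (24.2 ± 12.7 and 3.37 ± 3.85 FPKM), and Ugt3a1, a UDP-glycosyltransferase gene (29.0 ± 20.8 and 3.54 ± 3.37 FPKM), rose by 3.07 and 3.04 on the log2 scale, and Dmgdh, of choline breakdown, by 2.51 and Uroc1, of histidine breakdown, by 2.19. Members of the Slc and Slco families of solute carriers made up 8 of the 44 higher genes (Slc16a7, Slc22a19, Slc22a26, Slc22a7, Slc5a8, Slc7a12, Slc7a13 and Slco4c1) and none of the lower ones, out of 262 tested (Fisher's exact test, two-sided p = 1.06e-06, odds ratio 12.4). The family was picked because its members were seen among the higher genes, so the test only restates that, and the median log2 change of all 262 was 0.32.

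Among lower genes outside the lists, Ube2c fell from 10.3 ± 7.71 to 0.88 ± 0.767 FPKM (SD, n = 4 each, log2 change -2.89 ± 0.57, SE), and the mitotic motor and spindle genes Kif4, Cenpe and Tpx2 fell by 1.91, 1.91 and 2.20. The serine synthesis gene Phgdh fell from 23.9 ± 19.7 to 2.18 ± 1.54 FPKM (-2.95 ± 0.68). Il1rn, which encodes the interleukin 1 receptor antagonist, fell from 1.90 ± 0.553 to 0.158 ± 0.237 FPKM (-1.90 ± 0.40). Histone genes of the Hist1 and Hist2 clusters were 9 of the 87 lower genes out of 46 tested (Fisher's exact test, two-sided p = 6.27e-12, odds ratio 44.5), and 2 of the 9 belong to the histone list of the report. They share reads with near-identical copies and move together, and the family was picked in the same way, so the test adds no evidence.

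Nnt, which carries a deletion in C57BL/6J mice, was called higher for the gene model ENSMUSG00000116207 (14.4, 22.5, 2.93 and 6.09 FPKM in hypoxia libraries 1 to 4, and 0, 0, 7.85 and 0 in normoxia libraries 5 to 8). The model ENSMUSG00000025453, at almost the same position on chromosome 13 (119335448 to 119408997, against 119335528 to 119408952), was between 0.69 and 3.78 FPKM and did not pass (adjusted p = 0.977). Reads of the overlapping models cannot be divided from these values, and the call is uncertain.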
